A study of Homo sapiens with 3 samples.

How the data were processed

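RNA of K562 cells carrying the AAVS1 paired guide RNA was sequenced in 3 libraries, all of 1 group. Per the labels, the cells grew in RPMI medium with 10% fetal bovine serum, were infected with lentivirus at a multiplicity of infection below 1, and infected cells were sorted by flow cytometry 8 days after infection. Total RNA was column-purified and 2 µg entered each library, which was made by poly(A) selection, first- and second-strand synthesis and a DNA library kit. The names of the library modules do not mention strand marking. The labels mention replicates without saying how they were obtained, and do not name the nuclease or the guide sequences.

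The authors deposited 1 table per library of raw read counts per gene, with versioned Ensembl gene identifiers and no normalization. HISAT2 2.0.4, StringTie 1.3.5 and the human build hg19 are named in the submitters' processing notes, without their roles. The counter is not given in the sources used here, although the names of 5 summary entries are those that htseq-count writes, and the strand setting, annotation and filters are not given either. These summary entries name no gene and stayed out of library sizes and tests. In replicates 1, 2 and 3 they held 31.2%, 31.3% and 31.7% of all reads as falling in no gene, 29.0%, 29.0% and 28.6% as below the alignment quality limit, 13.5%, 13.3% and 12.9% as not aligned, and 0.814%, 0.815% and 0.846% as ambiguous. Reads in genes made up 25.5%, 25.6% and 25.9% of 48889625, 49562899 and 51137677 reads. Aligners give low quality to reads that fit several positions, so leaving out reads below the limit can lower genes with near-identical copies. A gene and an antisense gene across from it cannot be told apart without strand.

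Symbols, gene types, exon lengths and GC content came from GENCODE release 29 by identifier without its version, which matched 52338 of 57820 identifiers (90.5%) holding 99.0% of gene reads. Since that annotation lies on another build than the one named for the files, no coordinates are given. Expressed genes were those with at least 10 reads in each library. CPM were computed as counts per 1000000 gene-assigned reads and averaged over libraries with the SD. A count of 0 was taken to allow up to 3 reads.

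With a single group there is no contrast, so edgeR's quasi-likelihood test could not be used. Instead each gene's 3 counts were tested by chi-square against Poisson means proportional to effective library sizes (TMM, edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment over 15661 genes and a threshold of 0.05. This test concerns the reads of these libraries. It can call small spreads in genes with many reads, so the numbers of varying genes depend on depth. The common biological coefficient of variation came from edgeR with an intercept-only design, and pairs of libraries were compared by chi-square over genes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 25 gene lists (globin, erythroid, haem synthesis, 7 lists for other cell types, CTCF and cohesin, condensin, nuclear lamina, Polycomb, heterochromatin and DNA methylation, double-strand break repair, p53 targets, interferon response, unfolded protein response, cell cycle, apoptosis regulators, 9p21, AAVS1 host and neighbours, reference genes and nuclear long non-coding RNAs), the 12 gene pairs, the tests and the alternatives were fixed before the data were examined. Of 341 list entries 340 were matched; UHRF1 was not and has no value. The erythroid list was set against 7 lists by a two-sided permutation test of gene labels on the difference in median log2(CPM + 1), with 100000 draws and Benjamini-Hochberg adjustment over the 7. Log2 ratios of gene pairs were taken per library with 0.5 reads added to each side. Folds of the fetal globin genes over HBB are ratios of the counts with nothing added, and their intervals are 95% Clopper-Pearson intervals.

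The genes named in the text follow a rule. They are all globin, 9p21 and AAVS1-neighbour genes, up to 5 highest and 3 lowest genes by mean CPM of each other list, the 20 most abundant genes, the genes of the pairs, and, among varying genes with at least 50 reads in each library, the 10 with the largest chi-square and the 10 with the widest span. Genes named for their pseudogenes or for their overlaps, and others marked so, were chosen after their values were seen. Not every gene of the rule is printed.

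The gene-wise test was checked on simulated Poisson counts of 15661 genes, 50 at each fold changed in 1 library. It recovered 42% of genes changed 1.2-fold, 70% at 1.5-fold, 82% at 2-fold and 100% at 4-fold, with 7 false calls. A simulated coefficient of variation of 5% was recovered as 5.03%. The list test called 5% of 200 lists with no shift and 91.5% of 200 lists shifted by 3 on the log2 scale. These lists were drawn from the 15661 expressed genes. The lists compared in the results also hold genes near 0, which the check does not cover.

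The alternatives were DESeq2 1.42.0 size factors or total counts as scaling, minimums of 1 or 50 reads or none, thinning to the smallest library, an adjusted p of 0.01, DESeq2's dispersions, counts per kilobase of exon, other added values, and leaving out each replicate in turn. A GC correction of the gene-wise test and a comparison of library pairs at 50 reads were added after the data were seen. Groups of 3 libraries were not tested for outlying samples, and splits between groups do not arise. Long non-coding genes outside the lists, splicing and editing at AAVS1 were not analysed here.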

Results

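Gene expression was measured by RNA sequencing in K562 cells, a human erythroleukaemia line derived from chronic myeloid leukaemia in blast crisis. The cells carried a paired guide RNA against AAVS1, a site inside PPP1R12C on chromosome 19 that is widely used as a control target because edits there are tolerated. All 3 libraries belonged to this single group and were labelled replicates 1, 2 and 3. The series concerns non-coding loci and their part in chromatin organisation and viability, and in such a design cells edited at AAVS1 serve as the reference state. No untargeted or otherwise targeted cells were analysed here, so the questions asked were what these cells expressed, how AAVS1's host gene and its neighbours were expressed, and how closely the 3 libraries agreed. Reads assigned to genes numbered 12472858, 12682249 and 13237923 in replicates 1, 2 and 3. Nothing in the labels says that the replicates were separate cultures, so p-values for differences between libraries measure only the spread between these samples, which may be technical. Levels are counts per 1000000 gene-assigned reads (CPM), as mean ± SD over 3 libraries unless stated.

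PPP1R12C (ENSG00000125503.8), which encodes a regulatory subunit of myosin phosphatase and hosts AAVS1 in the first of its introns, was expressed in every library at 79.2 ± 4.02 CPM, from 1040, 956 and 1042 reads. It ranked 2965th among the expressed genes, and its counts did not differ between the libraries beyond counting noise (chi-square test, adjusted p = 0.128). Of its 29 listed neighbours on chromosome 19, 25 had at least 10 reads in each library, and PPP1R12C was the seventh most abundant of the 30 listed genes by CPM, above 23 of them, and the 14th per kilobase of exon. The stretch they span holds 35 protein-coding genes, so not all were listed. The highest neighbours were PPP6R1, a subunit of protein phosphatase 6, at 175 ± 24.0 CPM, the ubiquitin-conjugating enzyme UBE2S at 104 ± 10.1 and the zinc finger gene ZNF865 at 90.3 ± 11.9. UBE2S also has 318 CPM on its processed pseudogenes, so its own level is uncertain. RPL28, a ribosomal protein gene, stood at 89.1 ± 0.527 CPM and the histone methyltransferase gene KMT5C at 67.0 ± 1.72. TNNT1 and TNNI3, troponin genes of slow skeletal and cardiac muscle next to PPP1R12C, gave 31.7 ± 6.0 and 23.1 ± 5.91 CPM. DNAAF3 gave 28.9 ± 2.33 CPM, with 27.2% of its exons under an antisense gene. If the libraries do not mark strand, reads of that shared part cannot be told apart. TMEM150B, IL11, TMEM190 and SBK2 stayed under 10 reads in at least 1 library. Counts varied between libraries beyond counting noise for 11 of the 26 expressed genes of this list, or 12 when adjusted over the list alone, and 9 of the 11 were highest in replicate 1. After a correction for GC content 6 varied, of which 2 were highest in replicate 1 and 3 in replicate 2. The median GC content of the list was 63.0% against 48.5% for expressed genes. Among the 11, PPP6R1 had 2518 reads in replicate 1 against 1975 and 2216, and TNNI3 had 379 in replicate 2 against 246 and 259. Without replicate 2, 5 genes of the list varied. The read counts do not report whether AAVS1 was edited.

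**Figure D1:**
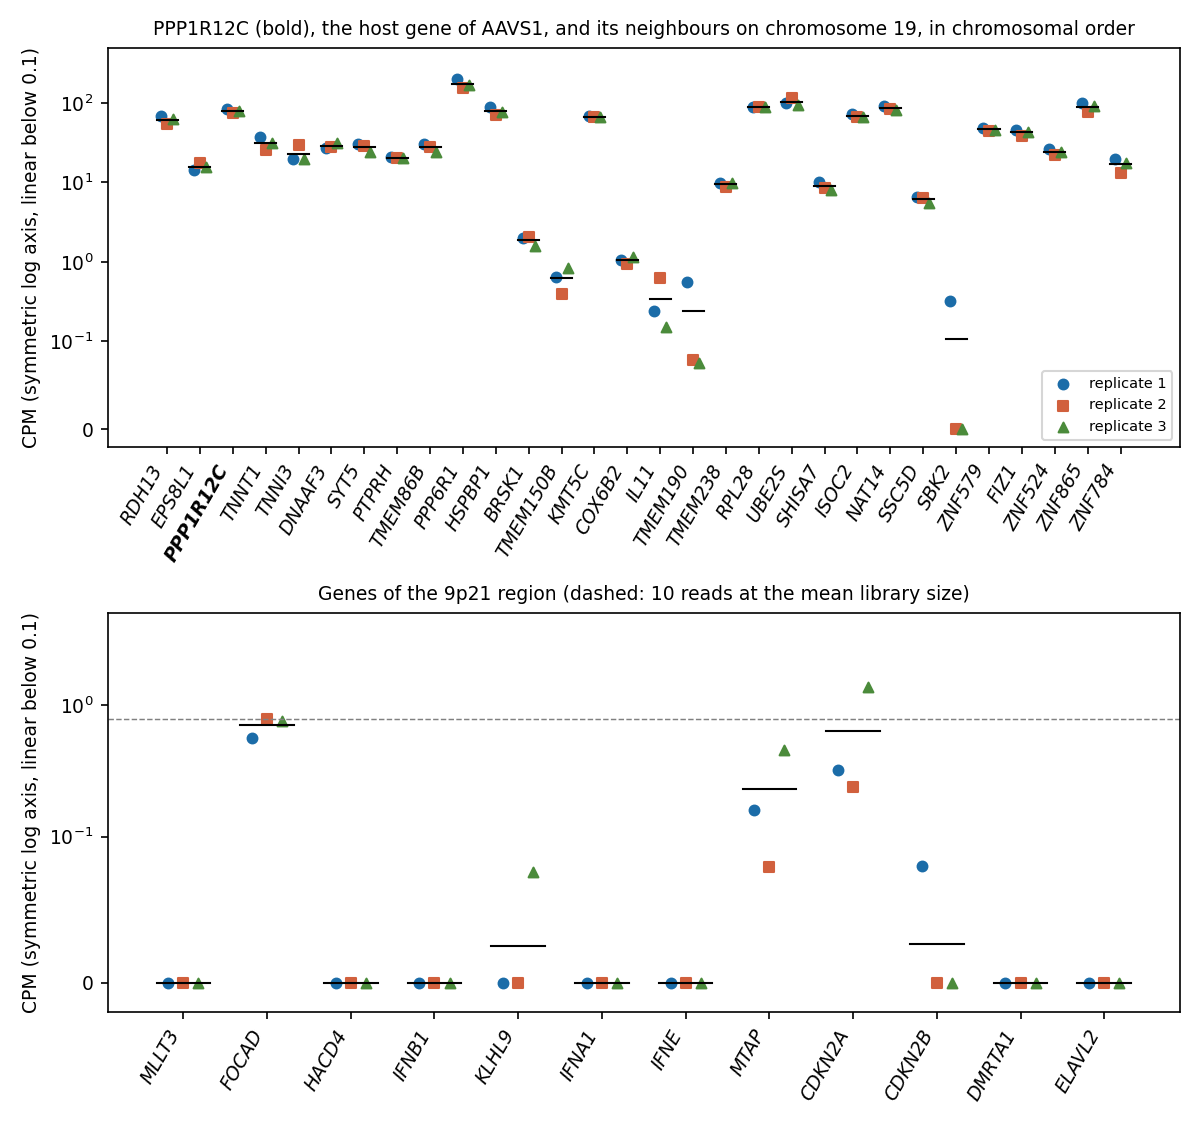
CPM of each gene (symmetric log axis) in replicates 1, 2 and 3 (circles, squares and triangles) with the mean as a bar, for PPP1R12C and its neighbours in chromosomal order (top) and for genes of the 9p21 region (bottom). PPP1R12C, at 79.2 CPM, ranks 7 of the 30 listed genes by CPM and 14 per kilobase of exon, while no listed 9p21 gene reached 10 reads in each library.

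A total of 15661 genes had at least 10 reads in each library, 11386 of them protein-coding and 1449 processed pseudogenes. Of 57820 listed genes, 30153 had no read in any library. At these depths a count of 0 allows up to 3 reads, or 0.241, 0.237 and 0.227 CPM in replicates 1, 2 and 3, and all such limits and intervals cover counting error only. The 100 most abundant genes took 23.7% ± 0.779 of the reads, and 13.8% once mitochondrially encoded and ribosomal RNA genes were left out of the total. MT-RNR2, the mitochondrial large ribosomal RNA, was the most abundant at 32177 ± 2064 CPM, followed by MT-ND4, a subunit of respiratory complex I, at 17738 CPM. The 13 mitochondrial messenger RNAs together took 8.99% ± 0.562. Among nuclear genes, EEF2, the elongation factor that moves the ribosome along, reached 3376 CPM and TUBB, a beta-tubulin, 3299. The linker histone gene H1-2 stood at 2951 CPM, PRAME, a tumour antigen common in leukaemia, at 2577 and the chromatin protein gene HMGA1 at 2559. Several of the most abundant entries were processed pseudogenes, led by RPLP0P6 at 4160 ± 415, RPL13AP5 at 3142 and HSP90AB3P at 2529 CPM. Their reads cannot be separated with certainty from those of the parent genes, and the counts of RPLP0 (160 ± 6.85 CPM), PPIA (180 ± 5.80) and GAPDH, with 823 CPM on its pseudogenes, are uncertain for the same reason. GAPDH and TUBB also have 14.2% and 16.0% of their exons under an antisense gene. The reference genes ACTB and GAPDH reached 2870 ± 138 and 1413 ± 49.97 CPM, against 33.7 ± 4.58 for HPRT1 and 19.3 ± 0.965 for TBP, and all 12 genes of that list were expressed. Of the nuclear long non-coding RNAs, MALAT1 stood at 2222 ± 122, NEAT1 at 1993 ± 73.2, TUG1 at 231 ± 12.8 and KCNQ1OT1 at 43.8 ± 6.56 CPM, while MEG3 had no read. XIST lay above TUG1, with 17494 reads over the 3 libraries against 8862, and 29.7% of its exons are under the opposite-strand gene TSIX. Some 5 of the 6 genes of that list were expressed, and all 5 varied beyond counting noise, also when adjusted over the list alone. With this many reads small spreads are called. The SD was 3.67% of the mean for NEAT1 and 5.48% for MALAT1.

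The globin genes showed an embryonic and fetal pattern. HBE1 (ENSG00000213931.1), the embryonic beta-like globin on chromosome 11, was the most abundant of them at 1533 ± 141 CPM, and the fetal genes HBG2 and HBG1 followed at 386 ± 104 and 250 ± 56.1. The adult gene HBB had 8, 15 and 1 reads and HBD, a minor adult gene, 62, 67 and 76. On chromosome 16, the alpha-globin genes HBA1 and HBA2 gave 249 ± 11.9 and 94.2 ± 15.2 CPM, the embryonic HBZ 137 ± 4.74 and HBQ1 17.2 ± 2.43, while HBM had 0, 1 and 2 reads. HBE1 exceeded the sum of HBG1 and HBG2 in all 3 libraries, with a log2 ratio of 1.29 ± 0.22. The fetal genes exceeded HBB 877-fold (95% Clopper-Pearson interval 445 to 2032) in replicate 1, 692-fold (419 to 1237) in replicate 2 and 6949-fold (1247 to 274510) in replicate 3, where a single HBB read sets the ratio. HBZ stood below the sum of HBA1 and HBA2 in all 3 libraries, with a log2 ratio of -1.32 ± 0.09. With 3 libraries a sign-flip permutation test cannot go below p = 0.25, so ratios are given without p. HBG1 and HBG2, like HBA1 and HBA2, are near-identical copies, and the division of reads within each such set is uncertain. Reads below the alignment quality limit were left out, which can also lower the sum of each set. The ratios that use these sums, and the place of HBE1 above the fetal genes, hold for the counted reads only. Of 8 expressed globin genes, 6 varied beyond counting noise, also when adjusted over the list alone. HBG2 had 6403 reads in replicate 2 against 4205 and 4170, a span of 1.58-fold between the highest and the lowest library. HBG1, with 3980 against 2809 and 2779, and HBE1 were likewise highest in replicate 2, while HBA1, HBA2 and HBQ1 were highest in replicate 1. Without replicate 2, 3 globin genes varied, and after a correction for GC content 5 did, of which 4 were highest in replicate 2 and 1 in replicate 1.

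**Figure D2:**
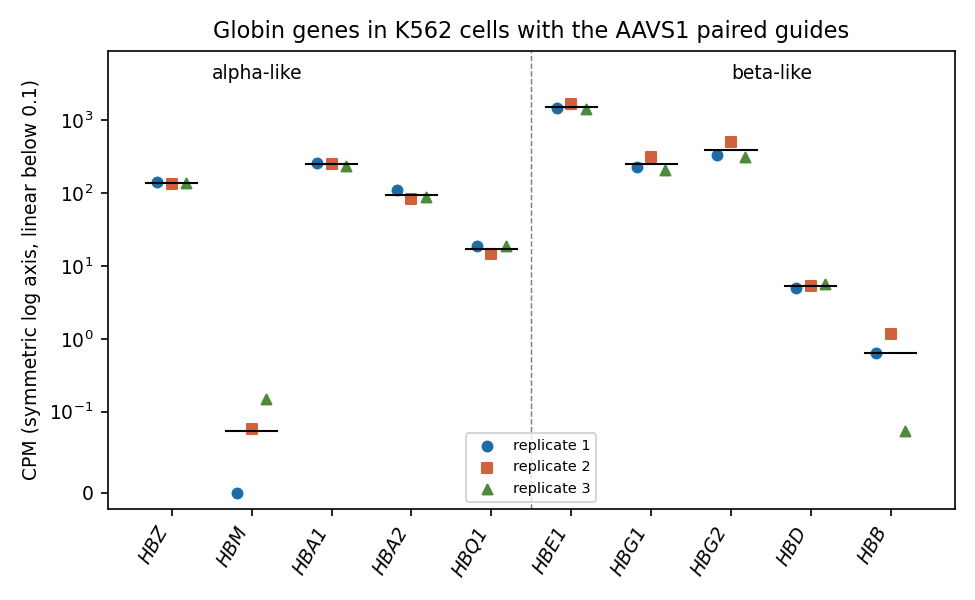
CPM of 10 globin genes (symmetric log axis) in replicates 1, 2 and 3, with the mean as a bar, alpha-like genes on the left and beta-like genes on the right. HBE1, at 1533 CPM, lies above HBG2 and HBG1 in each library, and HBB and HBM lie below the other genes.

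Erythroid genes were expressed throughout: all 21 members of the list had at least 10 reads in each library, with a median log2(CPM + 1) of 6.47. TFRC, the transferrin receptor, reached 911 ± 35.7 CPM, and the transcription factor genes NFE2, GATA1 and KLF1 reached 570 ± 28.2, 365 ± 18.2 and 326 ± 21.5. ANK1, which anchors the red cell membrane skeleton, gave 279 ± 6.86 CPM. The lowest members were SLC4A1, the anion exchanger, at 8.86 ± 0.864, EPB42 at 2.32 ± 0.302 and GYPB at 1.55 ± 0.673 CPM. Counts of 9 erythroid genes varied beyond counting noise, or 11 adjusted over the list alone, and without replicate 2 the number was 7. All 11 haem synthesis genes were expressed, at a median of 5.91. They ranged from the mitochondrial iron importer SLC25A37 at 602 ± 21.7 CPM through the enzyme genes UROD and FECH at 213 ± 9.11 and 138 ± 4.27 down to UROS at 18.8 ± 0.205, and 3 of them varied, also when adjusted over the list alone.

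The erythroid list lay above each of the 7 lists for other cell types. Its median exceeded that of the megakaryocyte list by 6.30 on the log2 scale, granulocyte and monocyte by 6.17, B cell by 5.15, T and NK cell by 6.23, stem and progenitor by 4.45, fibroblast by 6.36 and epithelial by 4.82. A two-sided permutation test of gene labels gave adjusted p of 7.0e-05, 0.000105, 7.0e-05, 0.0014, 0.00155, 7.0e-05 and 0.00389 in that order. The test runs across genes, which are not independent replicates. The lists were picked as markers of an erythroid line and of cell types that the culture should lack. The direction was thus foreseen from the choice of lists, and the p-values are no separate evidence of cell identity. When only genes with at least 10 reads in each library were kept, the difference from the megakaryocyte list was 2.57 (permutation adjusted p = 0.094) and from the stem and progenitor list 0.54 (0.649), and that from the epithelial list was -0.92 (0.687).

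The other lists differed in how many of their genes were expressed. In the megakaryocyte list 4 of 13 genes were expressed, led by TUBB1, a platelet tubulin, at 69.8 ± 4.61 and ITGA2B, the platelet integrin alpha IIb, at 68.5 ± 2.45 CPM, while 5 genes, PF4, PPBP and GP1BB among them, had no read. TUBB1 has 34.0% of its exons under a gene on the opposite strand. In the granulocyte and monocyte list 7 of 15 were expressed, with lysozyme (LYZ) at 100.5 ± 14.1 CPM, SPI1, the myeloid transcription factor PU.1, at 32.1 ± 4.34 and CD33 at 16.5 ± 1.05, whereas CTSG, S100A8 and S100A9 had no read. LYZ also has 34.0% of its exons under an opposite-strand gene. B cell genes were expressed in 6 of 10 cases, at most 16.5 ± 0.97 CPM for CD22, and T and NK cell genes in 1 of 13, CD3D at 5.20 ± 0.988. The stem and progenitor list had 6 of 12 expressed, with GATA2 at 590 ± 44.8, RUNX1 at 83.0 ± 1.97, MYB at 82.1 ± 0.515 and MECOM at 43.4 ± 2.02 CPM, against no read for FLT3, HOXA9 and PROM1. Of 10 fibroblast genes, FN1 (fibronectin) at 46.8 ± 4.67 and COL1A1 at 1.97 ± 0.999 CPM were expressed. The epithelial list had 5 of 10 expressed, the simple-epithelium keratins KRT8, KRT19 and KRT18 at 364 ± 25.8, 218 ± 19.3 and 166 ± 8.14 CPM, MUC1 at 7.68 ± 1.22 and EPCAM at 5.50 ± 1.32, while CDH1, KRT5 and KRT14 had no read. KRT8 and KRT18 overlap on opposite strands over 7.63% and 16.3% of their exons.

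**Figure D3:**
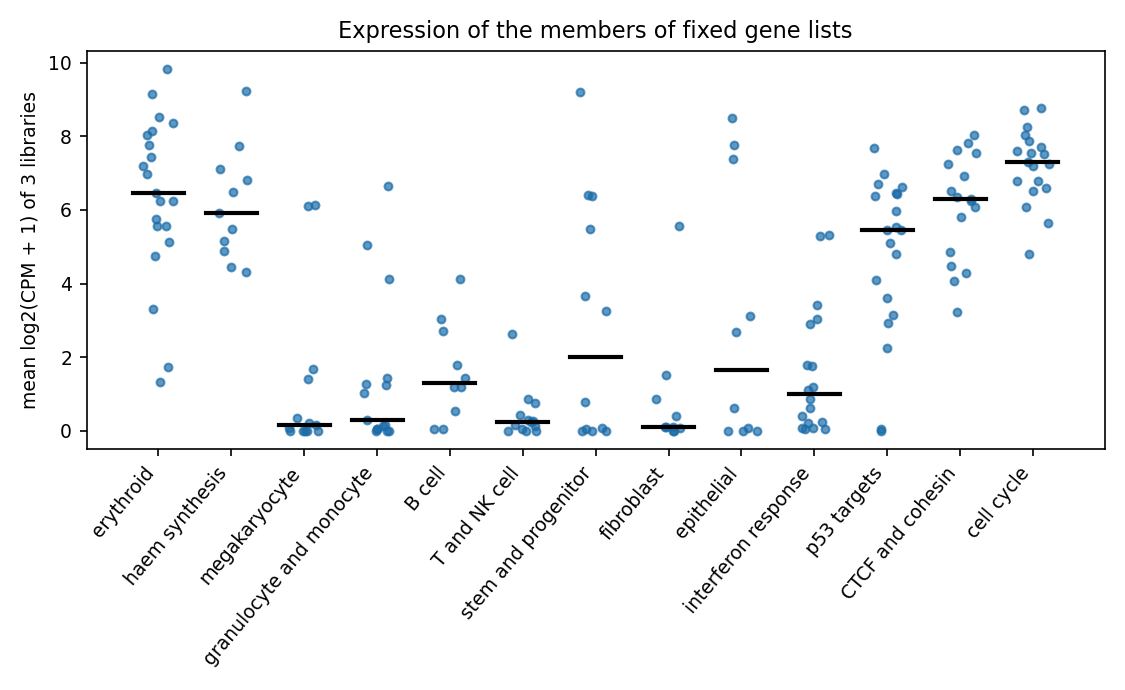
Mean log2(CPM + 1) over the 3 libraries for each member of 13 gene lists (points), with the median of each list as a bar. The erythroid list has its median at 6.47, and the lists for other cell types have medians of at most 2.01.

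Chosen gene pairs set related genes against each other within each library. GATA1 exceeded SPI1, its myeloid antagonist, by 3.51 ± 0.12 on the log2 scale. GATA1 stood at -0.69 ± 0.05 relative to GATA2 in read counts but at 0.88 per kilobase of exon. MYC reached 536 ± 35.1 CPM and MYCN had no read, so that MYC was at least 2392-fold, 2145-fold and 2319-fold higher in replicates 1, 2 and 3, set against the limit of 3 reads per library. BCL2L1, which encodes the survival protein BCL-XL, exceeded BCL2 by 6.99 ± 0.30. BCR on chromosome 22 stood at -1.27 ± 0.04 relative to ABL1 on chromosome 9. K562 cells carry the BCR-ABL1 fusion, and gene counts do not separate fusion transcripts from those of the unfused genes. CTCFL, a germline paralog of CTCF, was expressed at 257 ± 10.2 CPM, and CTCF stood at -1.78 ± 0.05 relative to it. STAG2 exceeded STAG1, the other cohesin subunit of its kind, by 3.41 ± 0.13, where 21.2% of STAG1's exons lie under an opposite-strand gene. EZH2 relative to EZH1, the alternative methyltransferases of Polycomb complex PRC2, was -0.11 ± 0.09 in read counts and 0.52 per kilobase, and LMNB1 relative to LMNA was -0.77 ± 0.05 and 0.17, so the direction of both depends on whether length is counted.

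Genes that organise chromatin were expressed almost without exception. All 17 genes of the CTCF and cohesin list were expressed, at a median log2(CPM + 1) of 6.30. YY1, which joins enhancers and promoters, stood at 261 ± 3.95 CPM, the cohesin core subunit SMC1A at 225 ± 14.3, and STAG1 was the lowest at 8.41 ± 0.528. Counts of 8 genes varied beyond counting noise, also when adjusted over the list alone, 6 of the 8 were highest in replicate 2, and 0 varied without replicate 2. After the GC correction 6 varied, 4 of them highest in replicate 2. Over all genes tested 5393 of 15661 varied, and 2050 of 16032 without replicate 2, where fewer libraries enter the test. The median GC content was 40.8% in this list and 44.5% in the condensin list, against 48.5% for expressed genes. The 8 condensin genes, led by SMC4 at 208 ± 12.7 and NCAPD3 at 75.3 ± 5.28 CPM, had a median of 5.72, and 6 varied, also when adjusted over the list alone. All 6 were highest in replicate 2, for example NCAPG with 875 reads against 649 and 753, and 0 varied without it. NCAPG has 33.1% and SMC4 18.5% of its exons under an opposite-strand gene. After the GC correction 3 condensin genes varied, 2 of them highest in replicate 2 and 1 in replicate 1. Nuclear lamina genes, 10 of 10 expressed, had a median of 7.47, with TMPO at 477 ± 14.7, LMNA at 358 ± 12.2 and LMNB2 at 336 ± 15.2 CPM; 6 varied, or 8 adjusted over the list alone, and 3 without replicate 2. In the Polycomb list all 14 genes were expressed, at a median of 6.03, from PHF19 at 186 ± 7.65 and BMI1 at 109 ± 8.63 down to CBX7 at 11.4 ± 3.37 CPM. Of these, 7 varied, or 8 adjusted over the list alone, 5 of the 7 were highest in replicate 2, and 1 varied without it. After the GC correction 4 varied, 2 of them highest in replicate 2. In the list of heterochromatin and DNA methylation genes, all 12 that could be matched were expressed, at a median of 6.48. TRIM28, the corepressor of zinc finger proteins, reached 833 ± 71.7 CPM, CBX5 (HP1 alpha) 273 ± 3.38 and the maintenance methyltransferase DNMT1 181 ± 7.49, while DNMT3A stood at 4.69 ± 0.310. Here 5 varied, or 6 adjusted over the list alone, and 2 without replicate 2.

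Genes that respond to double-strand breaks, to viral RNA or to stress were listed because the cells had been infected with lentivirus and given guides. Of 15 break-repair genes 14 were expressed, at a list median of 4.65, with the kinase gene PRKDC at 330 ± 13.9, PARP1 at 197 ± 25.3 and the Ku80 gene XRCC5 at 128 ± 11.01 CPM, and NHEJ1 at a total of 1 read. Counts of 7 varied, also when adjusted over the list alone, all 7 were highest in replicate 2, and 2 varied without it. After the GC correction 4 varied, 3 of them highest in replicate 2. Among p53 target genes 18 of 20 were expressed, at a median of 5.45, with GADD45A at 203 ± 6.01 and TNFRSF10B, a death receptor gene, at 126 ± 1.24 CPM. The cell cycle inhibitor CDKN1A gave 45.4 ± 6.48 CPM, outside the rule for named genes and chosen after its values were seen, and FAS was among the lowest at 3.77 ± 0.819. There, 4 varied, also when adjusted over the list alone, and 1 without replicate 2. Interferon response genes were low, with 9 of 18 expressed and a median of 0.99. ISG15, a ubiquitin-like protein gene, stood at 38.6 ± 2.31 CPM, and OAS1 and IFI44L had a total of 1 read each. In that list 3 varied, also when adjusted over the list alone, and 0 without replicate 2. All 12 unfolded protein response genes were expressed, at a median of 7.22, with the chaperone genes CALR at 674 ± 42.7, SDF2L1 at 467 ± 41.6 and HSPA5 at 372 ± 4.88 CPM. The chaperone gene HSP90B1 had 3323 reads in replicate 2 against 2132 and 2634. Of this list 8 varied, or 9 adjusted over the list alone, and 3 without replicate 2.

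Cell cycle genes were all expressed, 19 of 19, at a median of 7.29. The proliferation antigen gene MKI67 stood at 438 ± 19.98 CPM, the replicative helicase genes MCM4 and MCM7 at 417 ± 3.42 and 302 ± 21.8, and CCNE1 was the lowest at 26.7 ± 1.09. TYMS, thymidylate synthase, gave 261 ± 25.5 CPM with 39.1% of its exons under an opposite-strand gene. Counts of 11 varied, or 12 adjusted over the list alone, 7 of the 11 were highest in replicate 2, and 3 varied without it. Among the apoptosis regulators 9 of 10 were expressed, at a median of 5.43. The survival genes MCL1 and BCL2L1 led at 412 ± 13.9 and 353 ± 17.8 CPM, BCL2 stood at 2.80 ± 0.770, and BCL2A1 had no read. In this list 4 varied, or 5 adjusted over the list alone, 2 without replicate 2 and 2 after the GC correction.

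Genes of the 9p21 region of chromosome 9, which K562 cells are known to have lost in part, were at or near 0. None of the 12 listed genes reached 10 reads in each library and 7 had no read at all, namely MLLT3, HACD4, IFNB1, IFNA1, IFNE, DMRTA1 and ELAVL2. CDKN2A, the gene of the cell cycle inhibitors p16 and p14ARF, had 4, 3 and 18 reads, MTAP, an enzyme gene of methionine salvage, 2, 1 and 6, and FOCAD 7, 10 and 10. KLHL9 and CDKN2B had a total of 1 read each. The 18 reads of CDKN2A in replicate 3 were the highest count in the list, and its mean of 0.639 CPM had an SD of 0.626. Counts this low do not tell an absent gene from a silent one.

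The 3 libraries were closely similar across genes but not within counting noise. Pearson's r of log2(CPM + 1) across genes, which are not independent replicates, was 0.989 between replicates 1 and 2, 0.993 between 1 and 3 and 0.991 between 2 and 3. Chi-square per degree of freedom was 7.54, 4.07 and 6.40 for the same pairs, where counting noise alone gives 1, so no pair looked like one library deposited again. The common biological coefficient of variation was 9.21%. A chi-square test of each gene against counting noise found 5393 of 15661 genes (34.4%) past an adjusted p of 0.05, with a median span of 1.27-fold between the highest and the lowest library. Of these, 1336 spanned more than 1.5-fold and 555 more than 2-fold. Replicates 1, 2 and 3 were the highest library for 1898, 2218 and 1277 of the 5393 and the lowest for 1908, 2040 and 1445. RPLP1, a ribosomal stalk protein gene, had 4863 reads in replicate 2 against 2123 and 2138, and EIF5AL1, a copy of the translation factor gene EIF5A, had 177 against 63 and 55, the widest span among genes with at least 50 reads in each library, at 3.31-fold. RPS6P25 had 565 against 219 and 225, while FTH1P7 was lowest in replicate 2, with 142 against 335 and 346. Both are processed pseudogenes. For such copies and their parent genes the placement of reads is uncertain, so these spans need not be differences in expression. The mitochondrial gene MT-ATP6 had 44573 reads in replicate 2 against 52088 and 62665. Ribosomal protein genes took 0.758% of reads in replicate 2 and 0.653% ± 0.0916 on average. The number of varying genes fell to 2953 without replicate 1 and 2050 without replicate 2, where fewer libraries enter the test, and was 3936 of 15255 after a correction for GC content, added after the data were seen.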

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

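The GC correction and the comparison of library pairs at 50 reads were chosen after the data were seen; all other alternatives were fixed before. The number of expressed genes, from 12394 to 20446 over its alternatives, stayed within 1.5 times of 15661. The share of the 100 most abundant genes was 13.8% without mitochondrially encoded and ribosomal RNA genes. Varying genes numbered 3459 at an adjusted p of 0.01 and from 2050 to 4145 with 1 replicate left out, lowest without replicate 2 and 2953 without replicate 1, where fewer libraries enter the test. Other scalings and minimums gave 4872 to 5628 and the GC correction 3936. The coefficient of variation was 5.80% as the median of DESeq2's gene-wise estimates and from 6.71% to 10.9% with 1 replicate left out, lowest without replicate 2. The least similar pair of libraries gave 8.78 at 50 reads. With only genes of at least 10 reads in each library, the erythroid list exceeded the megakaryocyte list by 2.57 (permutation adjusted p = 0.094) and the stem and progenitor list by 0.54 (0.649), and its difference from the epithelial list was -0.92 (0.687). That setting drops the genes near 0 by construction, and for the T and NK cell and fibroblast lists it left under 3 genes and was not run. All 7 differences kept their direction and their side of the threshold per kilobase of exon, with 0.1 added to CPM and with each replicate left out. Per kilobase of exon, log2 ratios became 0.88 for GATA1 over GATA2, 0.52 for EZH2 over EZH1 and 0.17 for LMNB1 over LMNA, each of the opposite sign, and moved to -1.18 for HBZ over HBA1 and HBA2, 3.98 for GATA1 over SPI1, 8.82 for BCL2L1 over BCL2, -1.97 for CTCF over CTCFL, -2.25 for BCR over ABL1 and 13.5 for MYC over MYCN. The last was 10.4 with 5 reads added. As MYCN has no read, its value is set by the reads added and is no measured ratio. PPP1R12C stood at 20.6 per kilobase of exon, scaled as CPM. These shifts follow from the lengths divided by. Of 149 alternative values of list levels, 51 moved by more than the spread between libraries. No paired analysis was possible because there is 1 group.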

Other observations

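In this part, the tests chosen only after the results were seen are the excess of reads in no gene over reads in genes and the count of varying genes after a GC correction. The comparison of class shares in replicate 2 was not fixed beforehand either.

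The processed pseudogenes are copies of spliced messenger RNA set back into the genome, and in these counts many of them stood above the genes they derive from. Of 1173 families of a parent gene and the pseudogenes named after it, with at least 10 CPM, 176 had more reads on the pseudogenes than on the parent. Families of ribosomal protein genes made up 34 of these, out of 72 such families, with a median of 37.4% of a family's reads on the pseudogenes against 2.60% in other families. EEF1A1, the main elongation factor of translation, had 91.5 CPM against 1404 on its pseudogenes, PPIA (cyclophilin A) 180 against 947 and RPL13A 577 against 3317. All named genes here were chosen after their values were seen.

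Processed pseudogenes, 10203 entries, took 9.92% ± 0.431 of gene reads. Only the 4937 named after a parent gene were tested, and they held 66879 CPM together. The shares that follow are of that sum. For these pseudogenes, transcription unrelated to the parent's sequence was argued against. The 3409 of them that share under 10% of their 31-base words with the parent held 2.61% of the reads. Reads of the parent placed on the copy remain a candidate explanation: across 4937 pseudogenes, which are not independent replicates, the shared part of the sequence and the level rose together (Spearman's rho = 0.461, two-sided permutation p = 0.0001, the smallest that 10000 draws can give), and the 234 pseudogenes sharing at least 50% of words held 60.1% of the reads. Transcription of recent, and so similar, copies is not excluded by this. No biological explanation was tested, as the design has 1 group.

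Reads in no gene outnumbered reads in genes 1.22-fold in replicates 1 and 2 and 1.23-fold in replicate 3. A library that does not mark strand but is counted on one strand may lose about as many reads as it keeps, and would give an antisense gene the reads of the gene across from it. Among 175 genes with at least 90% of their exons under a well-covered opposite-strand gene, 173 had reads, and the median read density was 1.99 times that of the covering gene (quartiles 1.08 and 3.14). The value predicted for this explanation was 0.5 to 2, so it was met narrowly, and a correctly stranded count, for which under 0.1 was predicted, was argued against. The excess of 22.3% of gene reads over an equal division, which reads from introns or outside annotated exons could give, was seen before its test was set and decides nothing; no biological explanation was tested.

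Replicate 2 differed from the others by 6.97 chi-square per degree of freedom on average, against 4.07 between replicates 1 and 3, a ratio of 1.71. That measure is weighted to genes with many reads. The median absolute log2 ratio across genes separated the pairs less. It was 0.164 for replicates 1 and 2, 0.129 for 1 and 3 and 0.140 for 2 and 3. Library size was predicted to be the cause only if replicate 2 had the smallest or largest total, and its total lay between the others. Thinning all libraries to the same total left 1.72, but the measure already allows for totals, so thinning decided little. GC content as the whole cause was argued against by a correction after which the ratio was 1.92, against 1.72 before it over the same genes. Both sides of the ratio fell. The pairs with replicate 2 went from 7.07 to 6.07 and the pair of replicates 1 and 3 from 4.10 to 3.16. GC content did go with part of the differences between genes: across genes its Spearman's rho with the deviation of replicate 2 was -0.32 and with replicate 1 over replicate 3 it was 0.26, so the trend was not particular to replicate 2, and the correction took the varying genes from 5313 to 3936, of which 3424 were the same genes. Reads moving between parent genes and pseudogenes would make them move oppositely, but across 469 families rho was 0.103 (permutation p = 0.0259). That test weighs all families alike, and a GC trend shared by parents and copies was not removed from it. By share of reads 2 classes moved oppositely, a comparison that was not among the predictions. Ribosomal protein genes took 0.758% in replicate 2 against 0.611% and 0.589% in replicates 1 and 3, and processed pseudogenes 9.43% against 10.1% and 10.2%. The loss was larger than the gain, and nuclear protein-coding genes also moved, with 72.3% against 71.8% and 70.4%. Class shares therefore cannot show reads passing between parents and copies. The predicted opposite movement was not found across families, but with the limits of that test the explanation stays open. A trend with exon length, also tested, left 6.92 against 4.10; a difference in culture or handling stays open, and no biological explanation was tested.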
